A study of Rattus norvegicus with 6 samples.

How the data were processed

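Liver RNA of 6 rats, 3 given vehicle and 3 given ADBAQ, was measured on 1-colour Agilent arrays, 1 array per rat, with the treatment protocol describing separate animals. Per the file headers, the arrays were read with Agilent Feature Extraction 10.7.1.1 (the labels give 10.7), and the array design was built on the rat genome assembly rn4. The deposited scanner files hold intensity values on a linear scale: the processed signal, from which Feature Extraction had removed background, the median spot signal and the median local background. Their remaining columns used, of the kind other, are flags per the file headers: well above background, saturated and outlier. The deposited series table holds a ratio made by the authors, the processed signal divided by the array's 75th percentile, on a linear scale and not centred on genes. This was found by setting each column against that array's scanner values. Its column medians were 0.0967, 0.097 and 0.0983 for vehicle and 0.093, 0.0971 and 0.0952 for ADBAQ. It is near-identical to the scaling used here, so it gives no independent check.

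Each array held 61657 probes and 1319 control spots, 1 spot per probe. Probes were named through RefSeq accessions with a table of symbols, which gave names to 27460 probes of 15284 genes and left 34197 probes unnamed, 6746 of them with an Ensembl transcript accession. No coordinates were in that table, so no positions are given. The 75th percentile of the processed signal was 455, 461 and 433 on the vehicle arrays and 643, 570 and 596 on the ADBAQ arrays. Between 0 and 2 outlier spots per array were left out. The number of arrays limits the precision.

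Values were log2 of the processed signal minus the array's 75th percentile of it. Probes were kept if well above background on all 3 arrays of at least 1 group, which left 38695 probes and 11344 named genes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and p was adjusted by Benjamini-Hochberg over the probes kept, with a threshold of 0.05. A gene was represented by its probe with the highest mean signal over all arrays. Of 1096 called genes with several probes, 1034 had all probes in the same direction, and 3 had a called probe in the opposite direction. Where a probe was not well above background on any array of a group, the fold is a bound: the mean of the brighter group against the mean, per array, of the higher of the lowest signal among probes well above background and the dim probe's own. This held for 61 called genes in vehicle and 12 in ADBAQ. Values are log2 fold changes, ADBAQ minus vehicle, ± SE. For genes the SE is that of eBayes, which draws each probe's variance towards a common value, so it is not the plain spread between rats. In the part on results flagged for a closer look, the SE comes from the spread of the arrays alone.

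Before the data were examined, the groups, the test, the alternatives, 28 gene lists and 16 cell type lists were fixed from textbook knowledge, and so was the rule for naming genes. Named are the 10 largest increases and the 10 largest decreases among called genes whose groups did not overlap, up to 4 members of each list, and a few genes fixed by name. The increases are ranked by the log2 fold change as measured, which rests on dim values for genes not well above background in vehicle. By their bounds Scn4b (11.0-fold), Liph (10.7-fold), Defb1 (7.44-fold) and Mybl1 (6.19-fold) lie below genes such as Trib3 (16.3-fold), Abcc3 (15.4-fold) and Cyp1a2 (14.7-fold). The text gives values for part of the genes so picked, mostly those that stayed called with each array left out, which is a choice made after the values were seen. Another 3 of them are not reported here, though the list counts include them. Lists with at least 5 measured members were tested with camera of limma, with a preset correlation between genes of 0.01 and adjustment over the 44 lists. Its estimated correlation and the fry test were alternatives. Members were also counted with p adjusted over the list alone.

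The other alternatives were normexp background correction (offset 50), quantile normalization, centring on a median, no filter on dim probes, a filter requiring all 6 arrays, the series table, trend and robust in eBayes, array weights, the replicate number as a block, the mean of a gene's probes, and leaving out each array. The mean spot signal that normexp was to use is not in the files, and the median spot signal took its place. Slide could not be used as a block, because each slide held 1 group. Scaling to the spike-in controls was added after seeing the data. It shifts all genes of an array alike, so the change of a gene relative to other genes stays the same. The list test uses each gene's change over its error, and the same shift counts more for genes with little spread. List calls gained or lost with this scaling can therefore reflect the spread of the genes and not a change relative to other genes. The procedure was tested on simulated data of 11344 genes with 3 arrays per group. It called 0 of 67 genes changed by 0.5 on the log2 scale, 30 of 67 changed by 1 and 60 of 66 changed by 2. It called 2 unchanged genes beside them, and 0 genes and 0 lists with no gene changed. The simulated noise was independent for each probe, so the count of lists cannot test the preset correlation between genes. Only 200 genes were changed, fewer than were called in the data, which makes the adjusted threshold stricter. The shares called therefore do not give the power of the real comparison.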

Results

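Liver RNA from 6 male Sprague-Dawley rats was measured on 1-colour Agilent arrays, 1 array per rat. The rats were bought at 5 weeks of age. In 3 of them ADBAQ, the anthraquinone dye intermediate 1-amino-2,4-dibromoanthraquinone, had been given at 1000 mg/kg/day, and the other 3 had received vehicle. The labels disagree on both the vehicle and the time: the vehicle is named as purified water in one field and corn oil in another, and the treatment lasted 28 days in some fields and 9 weeks in another. Each array carried 61657 probes that were not controls, and between 62.1% and 65.3% of them were well above background on an array. None of these probes had a saturated spot, and the control spots, among them the spike-in controls, were not checked for this. The number of arrays limits the precision of what follows. All vehicle arrays were on one slide read on one scan day and all ADBAQ arrays on a second slide read on a second day, so slide, scan day and group cannot be told apart in any difference given here.

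The comparison of ADBAQ with vehicle asked which liver genes differed after exposure to this chemical. The largest increase was that of Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor, with a log2 fold change of 12.54 ± 0.68 (SE, n = 3 rats per group; adjusted p = 0.000908). Its probe was well above background on 1 of the 3 vehicle arrays, and the fold was 5973 as measured and 2288 with the dim values raised to the lowest detected signal of their array. Its log2 fold change was 8.66 with normexp background correction. Trim54 was at least 30.8-fold higher (adjusted p = 0.000238) and Cyp1b1, a further P450 of the same family, at least 20.2-fold higher (adjusted p = 0.00148). For both the probe was not well above background on any vehicle array. The same held for Scn4b, a sodium channel subunit, at least 11.0-fold higher, Liph, a lipase, at least 10.71-fold higher, Defb1, a beta defensin, at least 7.44-fold higher, and Mybl1, a transcription factor, at least 6.19-fold higher. These bounds hold for the processed signal alone: with normexp background correction, whose offset of 50 lowers the folds of dim probes, all of these stayed called but with log2 fold changes of 2.56 (Trim54), 2.47 (Cyp1b1), 1.51 (Scn4b), 1.63 (Liph), 1.29 (Defb1) and 0.91 (Mybl1). Gpx2, a glutathione peroxidase, rose 31.8-fold, Akr1b8, an aldo-keto reductase, 25.6-fold and Grin2c, a glutamate receptor subunit, 22.2-fold. The rise of Gpx2 passed the threshold with all 6 arrays (adjusted p = 0.0252) but not without vehicle replicate 1 or 3 or ADBAQ replicate 1 or 3, where the adjusted p lay between 0.0610 and 0.0763.

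Among the genes that fell, Lrtm2 had the largest change, at -6.17 ± 0.52 on the log2 scale (adjusted p = 0.00297). Cyp3a9, a cytochrome P450, changed by -5.34 ± 0.34, Inmt, an indolethylamine methyltransferase, by -5.28 ± 0.78 and A2m, the rat acute phase protein alpha-2-macroglobulin, by -4.80 ± 0.41. Mme, the membrane protease neprilysin, changed by -4.44 ± 0.21, Slc16a11, a monocarboxylate transporter family member, by -4.39 ± 0.30, and Lepr, the leptin receptor, by -3.90 ± 0.14. With normexp background correction Mme changed by -2.86 and Lepr by -2.59. Stac3 (-5.92 ± 1.16), Mmd2 (-5.38 ± 1.28) and Igfbp2, an insulin-like growth factor binding protein (-4.27 ± 0.89), had wider errors. The call of Stac3 was lost without vehicle replicate 2 or 3 or ADBAQ replicate 2 (highest adjusted p = 0.0671). The fall of Mmd2, whose probe was well above background on 1 ADBAQ array, was 41.5-fold as measured and 18.2-fold with dim values raised in the same way. Its call was lost without vehicle replicate 1 or 3 or ADBAQ replicate 1 or 3 (highest adjusted p = 0.104), with trend and robust (adjusted p = 0.0505) and with array weights (adjusted p = 0.0513). That of Igfbp2 was lost without vehicle replicate 2 or ADBAQ replicate 2 or 3 (highest adjusted p = 0.0748).

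Of 11344 genes tested, 2308 (20.4%) had an adjusted p under 0.05, 1027 higher and 1281 lower in ADBAQ. At least a 2-fold change was seen in 633 of these, 326 higher and 307 lower. In 5256 genes (46.3%) the 3 values of one group all lay above those of the other, where chance gives 10%. Of 19425 tested probes with no gene name, 3373 passed the threshold. Leaving out 1 array lowered the count to between 901 (without ADBAQ replicate 1) and 1543 (without vehicle replicate 1). These changes are relative to each array's 75th percentile. Scaled to the spike-in controls instead, an alternative chosen after seeing the data, the median of all genes lay at 0.695 on the log2 scale, and 8997 genes were called, 8800 higher and 197 lower. With normexp background correction the split was 1393 higher and 2649 lower, so that 34.5% of calls were higher against 44.5%.

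Targets of the aryl hydrocarbon receptor (AhR) rose as a list fixed in advance. Of 8 measured members 6 rose and none fell (7 and none adjusted over the list alone), with a median log2 fold change of 3.74 (camera adjusted p = 5.86e-06; adjusted p = 0.312 with an estimated correlation). Besides Cyp1a1 and Cyp1b1, Cyp1a2 rose by 3.88 ± 0.15 (adjusted p = 0.000403), Aldh3a1, an aldehyde dehydrogenase, by 3.71 ± 0.57, and Ahrr, the receptor's repressor, was at least 5.02-fold higher (0.74 on the log2 scale with normexp background correction). Nqo1, a quinone reductase, was higher on all 3 ADBAQ arrays but did not pass the threshold (1.85 ± 0.61, adjusted p = 0.0824). Of its 2 probes, both in this direction, the one not chosen passed. Its ADBAQ values ranged from 1.99 to 4.41 against 1.49 to 1.76 in vehicle, and the call was made with normexp background correction (adjusted p = 0.0328) or without ADBAQ replicate 2 (adjusted p = 0.00514). With genes at their bound the list median was 3.02. It was 2.17 with normexp background correction and 1.85 with only probes well above background on all 6 arrays. That filter leaves out the chosen probes of Cyp1a1, Cyp1b1 and Ahrr, so the last median covers fewer members and is not comparable with the others.

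**Figure D1:**
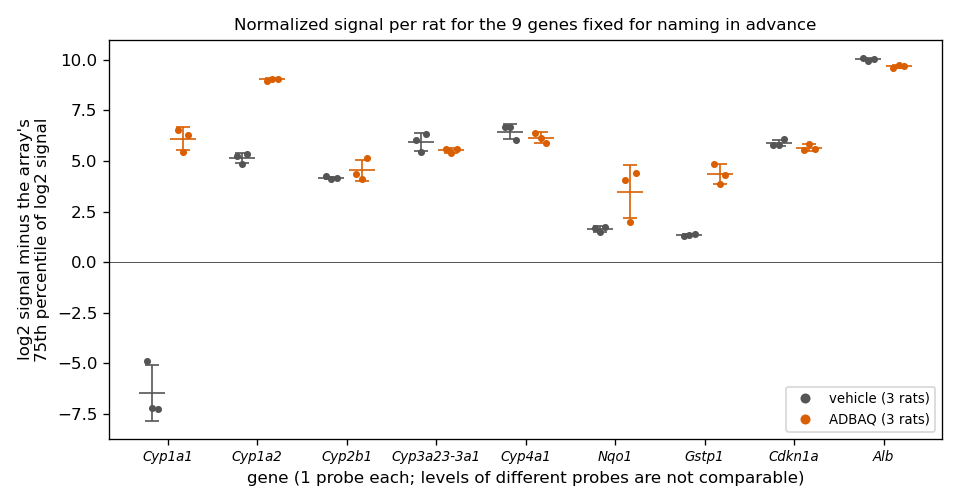
Normalized log2 signal (vertical axis, relative to each array's 75th percentile) of the 9 measured genes that were fixed for naming in advance, in 3 vehicle rats (grey) and 3 ADBAQ rats (orange); points are rats, horizontal bars means and error bars SD. Cyp1a1, Cyp1a2 and Gstp1 lay higher in every ADBAQ rat, Nqo1 ranged from 1.99 to 4.41 in the ADBAQ rats, and Cyp2b1, Cyp3a23-3a1, Cyp4a1 and Cdkn1a overlapped between the groups.

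Targets of NRF2, the transcription factor of the oxidant and electrophile response, rose with 24 of 32 measured members and none lower (26 and none adjusted over the list alone). The median was 1.16 (camera adjusted p = 1.01e-14; adjusted p = 0.0843 with an estimated correlation). Akr1b8 rose by 4.68 ± 0.56, the efflux pump gene Abcc3 by 3.95 ± 0.34 and Akr7a3, an aflatoxin aldehyde reductase, by 3.30 ± 0.28. Akr1b10 was at least 2.03-fold higher, and its call was lost with normexp background correction (0.38, adjusted p = 0.135). Glutathione transferases moved both ways, with 9 of 20 higher and 2 lower (10 and 3 adjusted over the list alone) and a median of 0.47 (camera adjusted p = 0.0055; adjusted p = 0.329 with an estimated correlation, and 0.57 when scaled to the spike-in controls). Gstp1, the placental form, rose by 2.99 ± 0.24 on its chosen probe, and 2 of its 3 measured probes had that direction. Gstm3 rose by 1.67 ± 0.29 and Gstm7 fell by 1.54 ± 0.20 on the log2 scale. The glucuronosyltransferase and sulfotransferase list had 6 of 20 higher and 4 lower (7 and 4 adjusted over the list alone) and was not called (adjusted p = 0.274). In it Ugt2b7 rose by 3.25 ± 0.40 and Sult2b1 by 1.70 ± 0.26, whereas Sult1c3 changed by -2.77 ± 0.19 and Ugt1a1 by -1.41 ± 0.15.

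Targets of CAR and PXR, receptors that respond to many drugs, went both ways, with 8 of 26 higher and 5 lower (11 and 6 adjusted over the list alone; camera adjusted p = 0.122). The list was called with normexp background correction (adjusted p = 0.0249) and with no filter on dim probes (adjusted p = 0.0315), and fry had an adjusted p of 0.0363. Cyp3a62 rose by 2.24 ± 0.10, while Slco1a4, an organic anion transporter, changed by -2.26 ± 0.24. Neither Cyp2b1 (0.37 ± 0.26, adjusted p = 0.339) nor Cyp3a23-3a1 (-0.40 ± 0.22, adjusted p = 0.244) passed the threshold. Among 34 PPAR alpha targets 3 rose and 5 fell (3 and 6 adjusted over the list alone; camera adjusted p = 0.0765). The list was called lower without vehicle replicate 3 (adjusted p = 0.00258) or ADBAQ replicate 1 (adjusted p = 0.0188), with array weights (adjusted p = 0.0493) and with the replicate block (adjusted p = 0.0244). Cyp4a1 did not pass the threshold (-0.31 ± 0.23, adjusted p = 0.365). Cd36, a fatty acid transporter, rose by 1.24 ± 0.19, and Acadm, an acyl-CoA dehydrogenase, changed by -0.66 ± 0.08. Fgf21, a fasting hormone, rose by 2.88 ± 0.63, a call lost without vehicle replicate 3 or any 1 ADBAQ array (highest adjusted p = 0.0909). Near-identical family members, such as those of the Ugt1a, Cyp2b, Cyp3a, Gsta, Mup and beta-globin families, are uncertain, because probe sequences were not examined for shared targets.

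Markers of preneoplastic foci in rat liver rose with 11 of 18 measured members and none lower (13 and none adjusted over the list alone; median 0.98; camera adjusted p = 5.86e-06; adjusted p = 0.123 with an estimated correlation, and 0.217 when scaled to the spike-in controls). Of these 18, 10 also stand in another fixed list. The NRF2 list shares 6 of them, all 6 called. The AhR list shares Aldh3a1 and the cholangiocyte list Prom1, both called as well. The cholangiocyte list also shares Krt19 and the fatty acid synthesis list Scd2, neither of them called. Most of the called members thus also stand in another list. Of the remaining members, Anxa2 rose by 1.73 and Cd44 by 1.02, while Afp (-0.16) and Gpc3 (-0.57) did not pass the threshold. These last members were chosen after their values were seen. The median of the preneoplastic list was 0.47 with normexp background correction. Targets of p53, the DNA damage response factor, rose with 11 of 25 and 1 lower (15 and 1 adjusted over the list alone; median 0.47; camera adjusted p = 7.05e-05; adjusted p = 0.123 with an estimated correlation). Ddit4 rose by 2.54 ± 0.24, Gadd45a by 1.73 ± 0.26, Mdm2, the p53 ubiquitin ligase, by 1.39 ± 0.13 and Ccng1 by 0.96 ± 0.12. Cdkn1a, the cell cycle inhibitor p21, did not pass the threshold (-0.23 ± 0.13, adjusted p = 0.25), and 1 of its 3 probes, the chosen one, had that direction.

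Cell cycle and mitosis genes had 8 of 36 higher and 1 lower (17 and 1 adjusted over the list alone), with a median of 0.71 (camera adjusted p = 7.25e-06; adjusted p = 0.582 with an estimated correlation, and 0.0729 when scaled to the spike-in controls). The spindle genes Tpx2 and Kif11 rose by 1.18 ± 0.17 and 0.97 ± 0.15, whereas Ccnd1, cyclin D1, named as the exception after its value was seen, changed by -0.95. With normexp background correction the value of Tpx2 was 0.01 (adjusted p = 0.967), that of Kif11 0.38 and the list median 0.27. Ttk rose by 1.57 ± 0.41, a call lost without vehicle replicate 2 or 3 or any 1 ADBAQ array (highest adjusted p = 0.127). Mki67 had no measured named probe. The DNA repair list was not called (3 of 25 higher and 1 lower, and 3 and 1 adjusted over the list alone; camera adjusted p = 0.151), except with no filter on dim probes (adjusted p = 0.0277). In it Apex1, an abasic site endonuclease, rose by 0.78 ± 0.12.

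Genes of the urea cycle and amino acid catabolism fell relative to the 75th percentile, with 25 of 36 lower and 1 higher (32 and 1 adjusted over the list alone). Their median was -0.65, and 0.09 when scaled to the spike-in controls (camera adjusted p = 7.70e-12; adjusted p = 0.0843 with an estimated correlation). Aass, of lysine breakdown, changed by -1.87 ± 0.08 (adjusted p = 0.000452), Gnmt, a glycine methyltransferase, by -1.43 ± 0.09, Kynu, of tryptophan breakdown, by -1.31 ± 0.12 and Cps1, the first enzyme of the urea cycle, by -1.21 ± 0.14. The exception was Tat, tyrosine aminotransferase, which rose by 1.14 ± 0.15. Markers of periportal hepatocytes fell with 7 of 13 lower (7 adjusted over the list alone), with a median of -0.66, and 0.08 when scaled to the spike-in controls (camera adjusted p = 5.24e-05; adjusted p = 0.181 with an estimated correlation). Of the 13, 6 also stand in the urea cycle list, 5 of them called. Hal and Ass1 changed by -1.04 ± 0.11 and -1.02 ± 0.12. General hepatocyte markers had 10 of 16 lower and 1 higher (12 and 1 adjusted over the list alone), with a median of -0.44, and 0.30 when scaled to the spike-in controls (camera adjusted p = 6.49e-05; adjusted p = 0.356 with an estimated correlation). This call was lost with quantile normalization (median -0.12, adjusted p = 0.16). Apoc3, an apolipoprotein, changed by -1.17 ± 0.11 and Apob by -0.67 ± 0.09. Alb, albumin, changed by -0.35 ± 0.09 (adjusted p = 0.0458), a call lost without any 1 of the 6 arrays (adjusted p from 0.0806 to 0.134) and with quantile normalization, where the value was 0.07. Pericentral hepatocyte markers were not called (2 of 15 higher and 5 lower, and 2 and 6 adjusted over the list alone; camera adjusted p = 0.108). They were called lower without ADBAQ replicate 2 (adjusted p = 0.0251) and with the replicate block (adjusted p = 0.0452). Scaled to the spike-in controls, the camera direction was lower (adjusted p = 4.51e-05) although the median was 0.32, which can reflect the spread of the genes. Oat, ornithine aminotransferase, changed by -1.83 ± 0.13.

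Cholesterol synthesis genes fell with 11 of 26 lower and none higher (14 and 1 adjusted over the list alone), with a median of -0.59, and 0.15 when scaled to the spike-in controls (camera adjusted p = 5.24e-05; adjusted p = 0.51 with an estimated correlation). Hmgcs1, HMG-CoA synthase, changed by -2.02 ± 0.20, Insig1 by -1.91 ± 0.30, Stard4 by -1.67 ± 0.09 and Idi1 by -1.45 ± 0.17. Bile acid synthesis and transport genes had 6 of 19 lower and 1 higher (7 and 1 adjusted over the list alone), with a median of -0.53, and 0.21 when scaled to the spike-in controls (camera adjusted p = 0.0136; adjusted p = 0.347 with an estimated correlation, and 0.0804 with normexp background correction). Slc27a5, a bile acid CoA ligase, changed by -2.17 ± 0.36 and the bile salt export pump gene Abcb11 by -0.86 ± 0.14, while the efflux pump gene Abcc4 rose by 1.90 ± 0.18. Gluconeogenesis and glycolysis genes had 11 of 24 lower and 1 higher (11 and 2 adjusted over the list alone), with a median of -0.34, and 0.40 when scaled to the spike-in controls (camera adjusted p = 0.00796; adjusted p = 0.184 with an estimated correlation, and 0.0563 with quantile normalization). Pfkfb1, Pklr (pyruvate kinase) and Gckr changed by -1.71 ± 0.26, -1.11 ± 0.10 and -1.06 ± 0.14. Fatty acid and triglyceride synthesis genes were not called (2 of 20 higher and 6 lower, the same adjusted over the list alone; camera adjusted p = 0.461), with Lpin1 at -1.28 ± 0.20 and Me1, malic enzyme, at 1.30 ± 0.21.

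**Figure D2:**
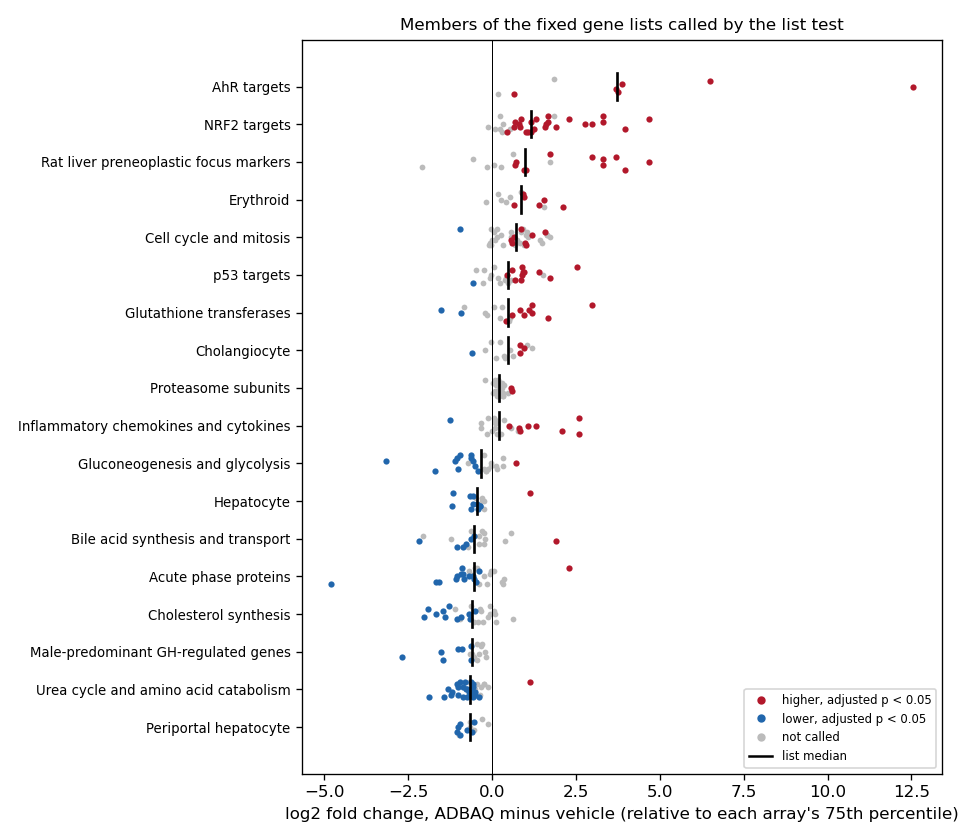
Log2 fold change (horizontal axis, ADBAQ minus vehicle, relative to each array's 75th percentile) of every measured member of the 18 fixed lists called by camera with a preset correlation; each point is 1 gene, red higher and blue lower with adjusted p under 0.05, grey not called, and black bars are list medians. Medians ran from -0.66 for periportal hepatocyte markers to 3.74 for AhR targets; scaled to the spike-in controls, the 8 lists with medians below 0 have medians above 0.

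Growth hormone regulated genes that are male-predominant in rats fell with 7 of 17 lower and none higher (12 and none adjusted over the list alone). The median was -0.59, and 0.14 when scaled to the spike-in controls (camera adjusted p = 5.96e-05; adjusted p = 0.184 with an estimated correlation). Cyp2c11, the main male-specific P450, changed by -2.68 ± 0.36 (adjusted p = 0.00852). The list fixed as female-predominant had 2 of 15 higher and 4 lower (4 and 4 adjusted over the list alone; camera adjusted p = 0.966). Car3, a carbonic anhydrase, changed by -3.50 ± 0.34 and Fmo1, a flavin monooxygenase, by -2.24 ± 0.21. Car3 is known as male-predominant in rat liver, and the place of Fmo1 and Ust5r in this list is uncertain, so these falls say little of female-predominant genes. Cyp2c12, the female-specific P450, rose by 1.43 ± 0.34, a call lost without any 1 vehicle array or ADBAQ replicate 1 or 3 (highest adjusted p = 0.0996). Thyroid hormone responsive genes (2 of 10 higher, 2 lower, the same adjusted over the list alone; camera adjusted p = 0.694) and circadian clock genes (none of 15 higher, 3 lower, and 2 and 6 adjusted over the list alone; camera adjusted p = 0.409) were not called. Fry called the clock list lower (adjusted p = 0.00693). In it Per1 changed by -1.56 ± 0.25.

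Acute phase proteins, made by the liver in inflammation, fell with 14 of 28 lower and 1 higher (20 and 1 adjusted over the list alone). The median was -0.53, and 0.20 when scaled to the spike-in controls (camera adjusted p = 3.34e-05; adjusted p = 0.456 with an estimated correlation). Besides A2m, Apcs, serum amyloid P, changed by -1.58 ± 0.13, and the exception was Lcn2, lipocalin 2, which rose by 2.29 ± 0.27. Inflammatory chemokines and cytokines rose with 8 of 24 higher and 1 lower (the same adjusted over the list alone; median 0.21; camera adjusted p = 0.0169; adjusted p = 0.456 with an estimated correlation, 0.0589 with only probes well above background on all 6 arrays, and 0.811 when scaled to the spike-in controls). Ccl7 was at least 1.88-fold and Cxcl2 at least 3.12-fold higher, and both calls were lost with normexp background correction (adjusted p = 0.31 and 0.131). Cxcl12, named as the exception after its value was seen, changed by -1.26. Interferon response genes were not called (3 of 28 higher and none lower, and 5 and 3 adjusted over the list alone; camera adjusted p = 0.824), with Rsad2 at 1.53 ± 0.18. Their median (-0.04) lay below 0 and their mean (0.02) and test direction above it.

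Proteasome subunits rose as a list, with a median of 0.22 (camera adjusted p = 5.86e-06; adjusted p = 0.456 with an estimated correlation), although 2 of 30 passed the threshold singly (2 adjusted over the list alone). Psmc4 rose by 0.57 ± 0.09. The endoplasmic reticulum and integrated stress list was not called (2 of 25 higher and 10 lower, and 3 and 13 adjusted over the list alone; camera adjusted p = 0.094). It was called lower without vehicle replicate 1 (adjusted p = 0.0141), with array weights (adjusted p = 0.0391) and with the replicate block (adjusted p = 0.0452). Scaled to the spike-in controls, the camera direction was lower (adjusted p = 1.86e-05) although the median was 0.24, which can reflect the spread of the genes. Its stress response genes Trib3 and Atf3 rose by 4.03 ± 0.34 and 3.10 ± 0.34, while the chaperone genes Hyou1 and Hsp90b1, chosen after their values were seen, changed by -0.99 and -0.87. Immediate early genes were not called (4 of 21 higher and 2 lower, and 7 and 5 adjusted over the list alone; camera adjusted p = 0.263), with Dusp1, a phosphatase, at -1.50 ± 0.14. Haem and iron genes were not called (3 of 24 higher and 3 lower, and 4 and 3 adjusted over the list alone; camera adjusted p = 0.757). Among them Hmox1, haem oxygenase, rose by 1.68 ± 0.25. Oxidative phosphorylation genes had none of 33 higher and 3 lower (none and 2 adjusted over the list alone; camera adjusted p = 0.0933), and were called lower without vehicle replicate 3 (adjusted p = 0.0181) or ADBAQ replicate 1 (adjusted p = 0.0482). Extracellular matrix genes had 1 of 21 higher and 5 lower (1 and 7 adjusted over the list alone; camera adjusted p = 0.0709), and were called lower without vehicle replicate 1 (adjusted p = 0.00776), with array weights (adjusted p = 0.0328) and by fry (adjusted p = 0.0168). Fn1, fibronectin, changed by -1.23 ± 0.09 and Ccn2 by -0.89 ± 0.09.

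Erythroid markers rose with 6 of 13 higher and none lower (the same adjusted over the list alone; median 0.87; camera adjusted p = 0.000843; adjusted p = 0.347 with an estimated correlation, and 0.404 when scaled to the spike-in controls). With normexp background correction the median was 0.17 (adjusted p = 0.0249). Ahsp, the alpha-haemoglobin chaperone, rose by 2.11 ± 0.35. Hbb, beta-globin, rose by 0.95 ± 0.17, a call lost without ADBAQ replicate 1 or 3 (adjusted p = 0.0618 and 0.0601). Cholangiocyte markers rose with 3 of 14 higher and 1 lower (6 and 1 adjusted over the list alone; median 0.46; camera adjusted p = 0.0235; adjusted p = 0.582 with an estimated correlation, 0.072 without ADBAQ replicate 3 and 0.635 when scaled to the spike-in controls). Prom1 (0.94), Cftr (0.83) and Epcam (0.82) rose, and the keratin gene Krt7 changed by -0.61. Each of these 4 calls was lost with some array left out, and that of Cftr also with normexp background correction (0.14, adjusted p = 0.242). Kupffer cell and macrophage markers were not called (3 of 20 higher and none lower, the same adjusted over the list alone; camera adjusted p = 0.122), except without ADBAQ replicate 2 (adjusted p = 0.0299) and with no filter on dim probes (adjusted p = 0.0349). Lyz2, lysozyme, rose by 0.88 ± 0.14, and Trem2 rose by 1.19 ± 0.12 but not with normexp background correction (0.16, adjusted p = 0.159). Endothelial markers had no member called of 14 (none adjusted over the list alone; camera adjusted p = 0.461), Pecam1 having the smallest p (-0.33 ± 0.09, adjusted p = 0.0584, and between 0.0313 and 0.0438 with normexp, without the filter on dim probes or with trend and robust). Stellate cell and fibroblast markers had 1 of 16 higher and 2 lower (the same adjusted over the list alone; camera adjusted p = 0.354), with Tagln at -0.61 ± 0.09.

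The remaining cell type lists were not called. T and NK cell markers had 2 of 20 lower (1 adjusted over the list alone; camera adjusted p = 0.532), with Gzma, a cytotoxic granule protease, at -1.31 ± 0.21. B and plasma cell markers had 2 of 8 lower (the same adjusted over the list alone; camera adjusted p = 0.218), with Mzb1 at -1.40 ± 0.20. Class II antigen presenting cell markers had 1 of 9 lower (the same adjusted over the list alone; camera adjusted p = 0.794). Neutrophil and myeloid markers (9 measured; camera adjusted p = 0.409), mast cell markers (8; 0.793), exocrine pancreas markers (9; 0.98) and adipocyte markers (8; 0.793) each had 1 member higher and 1 lower. Adjusted over the list alone these were the same, except for 2 lower in the mast cell list. Rnase1 of the pancreas list rose by 2.22 ± 0.20 and Lpl of the adipocyte list by 0.81 ± 0.12. With normexp background correction Rnase1 rose by 0.76 and the call of Lpl was lost (0.24, adjusted p = 0.0543). Platelet markers had no member called of 5 (none adjusted over the list alone; camera adjusted p = 0.409), Gp9 having the smallest p (0.36 ± 0.16, adjusted p = 0.166). In the pancreas list the median lay below 0 and the test direction above it, and the adipocyte list's median (-0.11) lay below 0 with its mean (0.05) and test direction above it. The mean of the thyroid hormone list (0.09) lay above 0 with its median (-0.20) and test direction below it.

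Of the 44 lists, 18 passed the threshold with the preset correlation of camera, 10 higher and 8 lower, and none with an estimated correlation, where the smallest adjusted p was 0.0843 and 7 lists had an unadjusted p under 0.05. The fry test of limma, which does not compare a list with other genes, called 19 lists. Its adjusted p was 0.103 for cell cycle genes, 0.0963 for chemokines and 0.103 for cholangiocyte markers. Scaled to the spike-in controls, 22 lists were called, 12 of them among the 18. Splits of the same 6 arrays that mix the groups gave between 7 and 23 called lists but at most 1 called gene. Each side then holds arrays of both groups, so the group difference adds to the spread within sides and lowers the gene count. Part of that difference stays between the sides, so neither count shows what chance gives.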

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

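All tests in this part were chosen after the results were seen. The spike-in controls, used above only for an alternative scaling, differed between the groups. The 75th percentile of the sample signal minus the mean of the 5 brightest spike-in controls was higher in ADBAQ by 0.733 on the log2 scale (SE 0.0337, n = 3 rats per group; exact permutation p = 0.1, two-sided, the smallest possible with 3 against 3). A uniformly brighter scan or hybridisation of the ADBAQ slide would cancel from this difference if the spike-in signal rose in proportion. The control spots were not checked for saturation, so the cancelling alone does not rule it out. The spike-in controls themselves differed by -0.311 (SE 0.0503). A uniformly brighter slide alone would not lower them, even with saturated spots, so this value argues against it. A scan or hybridisation that acts differently on spike-in and sample RNA was not tested, because each slide held 1 group. A few bright probes cannot set the 75th percentile of 61657 probes, so this needed no test. The unscaled signal rose in each of 5 brightness bins of the tested probes, by 0.364 in the bin with the smallest rise. The rise was thus not confined to bright probes. A different ratio of spike-in to sample RNA in the labelling of the ADBAQ arrays and an effect of the treatment on the RNA cannot be told apart, because each slide held 1 group.

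Hepatocyte markers were lower in ADBAQ relative to other genes, with a mean shift of -0.427 on the log2 scale (SE 0.0604). A lower share of hepatocytes would raise the markers of every other resident cell type alike. Their lists shifted by 0.444 (cholangiocyte, SE 0.222), 0.223 (Kupffer cell, SE 0.0719), -0.0945 (endothelial, SE 0.108) and -0.12 (stellate, SE 0.069). Of the 6 pairs of these lists, 2 had a 95% interval that leaves out 0, cholangiocyte minus endothelial (0.539, SE 0.158) and Kupffer cell minus stellate (0.343, SE 0.11), which counts against it, but 0 pairs did with the interval adjusted over the pairs, a bound set after the values were seen, so it stays open. Scaling to the 75th percentile moves all genes of an array by the same shift and cannot lower hepatocyte markers relative to other genes. The hepatocyte median minus that of all genes was -0.397 with it, with centring on a median and with the spike-in controls. It was -0.376 with normexp and -0.112 with quantile normalization, so how much of the fall depends on signal level stays open. Changed transcription in hepatocytes stays open too.

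Erythroid markers were higher in ADBAQ. More blood of unchanged composition would raise globin and other erythroid genes by the same amount, and the rise of the other erythroid genes minus that of the globin genes was -0.117 (SE 0.133), so it stays open, as white cells living in the liver could hide the few that blood brings. The globin genes here were only Hbb and Hbb-b1, 2 beta-globin genes whose probes were not examined for shared targets. The 8 others included Tfrc, which also stands in the haem and iron list. A larger number of all blood cells in the tissue, resident ones included, would raise the other blood lists as much, and the erythroid shift was larger than theirs by 0.63 (platelet, SE 0.228), 0.169 (neutrophil, SE 0.197), 1.00 (T and NK cell, SE 0.247) and 1.16 (B and plasma cell, SE 0.18). Of these 4 differences, 1 had a 95% interval adjusted over the lists that leaves out 0. It was that to the B and plasma cell list (0.386 to 1.94), which counts against a rise of all blood cells alike. The difference to the neutrophil list was smaller than its SE. The rule first used, on the platelet and neutrophil lists, left this explanation open. Both rules were set after the values were seen, so a rise of all blood cells alike stays open. A rise of some kinds of blood cell and a treatment effect on erythroid cells stay open too.

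With 3 arrays against 3 there are 10 splits of the 6 arrays, too few for a share under 0.05. Each of the other splits also has arrays of both groups on each side. Any group difference then widens the spread within sides and lowers the gene count, so a low count there says nothing of chance. Part of that difference stays between the sides, so the list counts are no chance rate either. The real split gave 2308 called genes (1027 higher, 1281 lower, 633 at least 2-fold), and the highest of the other splits gave 1 for each of these counts, either direction being read as higher. For the fixed lists the real split gave 18 and the highest of the others 23, and 4 of the 10 splits, the real one included, gave 18 or more.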

How the results depend on the processing

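Of 150 called named genes, 96 stayed called with each array left out in turn, and 54 lost the call with at least 1 array left out, between 21 (without vehicle replicate 1) and 49 (without ADBAQ replicate 1). No called named gene changed direction there. Leaving out 1 array gave 901 to 1543 called genes, 396 to 703 higher and 505 to 840 lower. Of the 18 called lists, 17 stayed called in each of these. Normexp background correction gave 4042 called genes, 2649 lower and 382 at least 2-fold. It lowered the log2 fold changes of dim genes, among those of the report Ugt2b7 to 1.71, Sult2b1 to 0.61, Ttk to 0.48, Per1 to -0.995, Mzb1 to -0.60, and Mmd2 to -2.67. The cholangiocyte median became 0.27 and that of chemokines 0.14. Quantile normalization gave medians of -0.32 (acute phase), -0.39 (male-predominant) and -0.18 (gluconeogenesis). No filter on dim probes gave 3530, with 2387 lower. The replicate number as a block gave 982 (429 higher, 553 lower), although the labels do not pair the rats. With it 39 named genes lost their call and kept their direction, among them Gpx2 (adjusted p = 0.0804), Mmd2 (0.0903), Scn4b (0.0528), Slc27a5 (0.0563) and Fgf21 (0.0749). Quantile normalization turned Alb to 0.067. With an estimated correlation 0 lists were called. With fry the female-predominant list, with a median of 0.39, was called in the lower direction (adjusted p = 0.00213). Slide as a block was not run, because each slide held 1 group.

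Scaling to the spike-in controls, added after seeing the data, gave 8997 called genes, 8800 higher, 197 lower and 2420 at least 2-fold. Its construction moves each gene by the same shift, and the median of all genes was 0.695. The list test weighs each gene's change by its error, so list calls gained or lost with this scaling can reflect the genes' spread. List medians became 0.15 (cholesterol synthesis), 0.21 (bile acids), 0.20 (acute phase), 0.40 (gluconeogenesis), 0.087 (urea cycle), 0.14 (male-predominant), 0.30 (hepatocyte) and 0.076 (periportal). The female-predominant list had 1.13 with a test in the lower direction. Of the 18 called lists, 12 were called with it. The 6 that were not had adjusted p = 0.0729 (cell cycle), 0.635 (cholangiocyte), 0.404 (erythroid), 0.57 (glutathione transferases), 0.811 (chemokines) and 0.217 (preneoplastic foci). It also called 10 lists that were not called before: pericentral, endoplasmic reticulum stress, PPAR alpha, extracellular matrix, circadian, mast cell, thyroid, fatty acid synthesis, B and plasma cell and female-predominant. Genes that turned were Acadm 0.070, Ung 0.17, Usp2 0.062, Ndufa1 0.295, Ndufa2 0.35, Ndufa4 0.41, Apob 0.060, Krt7 0.12, Tagln 0.12, Pdgfra 0.19, Pecam1 0.41, Clec9a 0.037, Pax5 0.069, Prtn3 0.20, Cdkn1a 0.51 and Alb 0.38. With this scaling 20 named genes lost their call and kept their direction, among them Abcb11 -0.13 (adjusted p = 0.47), Ccn2 -0.15 (0.178), Ass1 -0.29 (0.0783), Hal -0.30 (0.0568) and Gckr -0.33 (0.0555), and Cyp2b1, Gp9 and Nqo1 were called higher. Of the genes that turned, Cdkn1a (adjusted p = 0.00793), Pecam1 (0.0104), Alb (0.0115), Ndufa1 (0.0219), Ndufa2 (0.00875) and Ndufa4 (0.00734) were called higher with it. For the other alternatives the cause was not tested. Dim signal limits the folds of genes not well above background in 1 group, which are bounds.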

Other observations

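The genes in this part were chosen after their values were seen, and no enrichment was tested for them. Their values under the alternatives, normexp background correction and leaving out 1 array among them, were not examined. The bounds given here therefore hold for the processed signal alone. Mybl2, a transcription factor of the cell cycle, was higher in ADBAQ, with a log2 fold change of 4.05 ± 0.32 (SE, n = 3 rats per group; adjusted p = 0.00234), its probe being well above background on 1 of 3 vehicle arrays (16.6-fold as measured and 14.1-fold with dim values raised to the floor). Gtse1 rose by 1.97 ± 0.23 (adjusted p = 0.00605), while Mcm10, a DNA replication factor, changed by -1.51 ± 0.23. Nrg1, the growth factor neuregulin, rose by 3.36 ± 0.29 and Alox15, a lipoxygenase, by 2.68 ± 0.36. Mmp12, a macrophage metalloelastase, was at least 5.31-fold higher. Fabp2, the intestinal fatty acid binding protein, rose by 2.37 ± 0.35 (adjusted p = 0.0103), and Slc15a1, a peptide transporter, was at least 2.10-fold higher.

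Among other genes that fell, Apoa4, an apolipoprotein, changed by -3.08 ± 0.19 (adjusted p = 0.00129). Nox4, an NADPH oxidase, changed by -3.41 ± 0.41 and Notum, a Wnt inhibitor, by -2.72 ± 0.37. The aldo-keto reductases Akr1c1 and Akr1c2 changed by -3.44 ± 0.69 and -2.74 ± 0.51, and the steroid dehydrogenases Hsd3b1 and Hsd3b2 by -1.63 ± 0.31 and -1.61 ± 0.30. The members of each of these pairs belong to the same gene family, and their probes were not examined for shared targets.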
